A study of Homo sapiens with 11 samples.

How the data were processed

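RNA was taken from liver tumours that grew after PANC1 LM3 cells were placed in the spleen, in 11 libraries: 4 with a control hairpin (shCTRL), 3 with the NPTX1 hairpin shNPTX1_3 and 4 with the NPTX1 hairpin shNPTX1_4. Per the labels' protocols, total RNA was purified with a Norgen kit and libraries were made with the TruSeq RNA kit, version 2. The submitters' processing notes list STAR 2.7.6a, featureCounts 2.0.0, MultiQC 1.9 and DESeq2 1.24, and the genome builds hg19 and mm39 (human and mouse), without saying what each was used for. The gene annotation, the strand setting of the counting, and whether mouse reads were removed before counting are not given in the sources used here. No coordinates are printed, since the annotation used here is of another build.

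The authors' deposited table holds results, not reads. Per the file headers, it gives for each gene the mean of each group, the mean over all libraries, a log2 fold change with its standard error, a Wald statistic, a p-value and an adjusted p, in the column names of a DESeq2 results table. The group means are a signal that is never negative: counts divided by library size factors and averaged over the libraries of a group by the authors before the table was deposited. The log2 fold change of the authors' deposited table is that of the 7 knockdown libraries as 1 group over the 4 control libraries. It differed from the log2 ratio of the group means by a median of 0.00401 over 16437 rows with a mean of at least 10 normalized counts. The Wald statistic, a score in the authors' deposited table, equals the log2 fold change over its standard error. The p-value and adjusted p in the authors' deposited table are taken to be those of DESeq2, per the submitters' processing notes. In 21894 of 21898 rows the mean over all libraries equalled the group means weighted by 4, 3 and 4 libraries, within a relative difference of 1e-06, and in 4 rows it did not.

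Of 23434 rows, 107 were left out: 79 without a gene name, 26 named by a calendar date (a spreadsheet conversion of gene names) and 2 with a repeated name. They held 0.387% of the mean normalized counts, and 23 of them passed the threshold. Of all rows, 18509 had an adjusted p, 3383 had a p without an adjusted p, 6 had a fold change without a p, and 1536 were at 0 in every library. The named genes with an adjusted p numbered 18426. The group means summed to 18734000, 19997100 and 19323200 normalized counts in shCTRL, shNPTX1_3 and shNPTX1_4.

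Depth was read from the low group means, where a single read in 1 library gives a fixed step. With the steps found, 84.5%, 74.4% and 79.1% of the low values in shCTRL, shNPTX1_3 and shNPTX1_4 were whole reads within 2e-05 normalized counts, against 0.41%, 0.09% and 0.44% of random values. Reads per single library cannot be rebuilt from a group mean for most genes, so no count test was run. At the median standard error of 0.125 of genes at 2 CPM or more (38.6 normalized counts, CPM being normalized counts relative to the mean total of the table), small changes could pass the test, while genes near the lower end of the table carried much wider errors. Deeper libraries weigh no more than shallow ones in a group mean, so the shallow libraries set part of the error.

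The planned edgeR test of counts, with the design fixed before the data were examined, was replaced by the comparison in the authors' deposited table, because the values are group means. For the same reason there was no test per library, no exact permutation test between groups, no other grouping of the libraries and no test of a single gene for 1 hairpin alone. Genes were called at an adjusted p under 0.05 in the authors' deposited table.

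For each hairpin, the log2 ratio of group means was computed with a pseudocount of 1, which understates the change of low genes, for 14127 genes with a mean over all libraries of at least 2 CPM and no group at 0. Genes at least 2-fold apart were counted, with no test per gene. This minimum was set at 1 CPM in a first run and then raised to 2, to match the minimum of the rule for named genes, and the counts at 1 CPM are given in the closing section. The counts were set beside 20 simulated draws with no change in any group and 20 with the hairpins alike, drawn from the recovered size factors and from dispersions rebuilt from the standard errors in the authors' deposited table. A z for the difference between the hairpins was rebuilt in the same way. In the simulations each gene was drawn on its own, so spread that genes of a library share is absent from them. On simulated data for 14127 genes, 200 were changed between shNPTX1_4 and shNPTX1_3. Of these, 91% of genes changed 2-fold and 97% of genes changed 4-fold were recovered, and 16 unchanged genes were called. The dispersions were known in that simulation, while those rebuilt from the data already contain the difference between the hairpins. These shares therefore do not hold for the data, where 0 genes passed adjustment.

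The gene lists and the cell type markers, described by name in the report, were fixed before the data were examined. Lists with at least 3 tested genes were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistics of the authors' deposited table, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 19 gene lists and, separately, 7 marker lists. An estimated correlation and the rotation test fry need values per library, and were not run. The difference between the hairpins was tested over the same lists with cameraPR on the rebuilt z. On simulated data for 18426 genes and 100 draws, 2.68% of unchanged lists passed 0.05 before adjustment. Of lists shifted by 1 unit of the statistic, 97.6% were called. The simulated statistics were independent standard normal values. Wald statistics of the data are wider and genes of a list can vary together, so these shares are not error rates for the data.

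Chromosomes, gene order, transcript length and GC content came from GENCODE release 29, matched by gene name. Of the tested genes, 97.0% had a chromosome and 85.9% a length and GC content. Windows of 30 neighbouring genes were compared with 1000 permutations of gene positions; on simulated data for 13773 genes, 68% of windows shifted by 0.3 were found, with 3 other windows found in 100 draws. For an alternative of the list tests, level, transcript length and GC content were removed from the Wald statistic. For each of them in turn, the median of bins of like genes was subtracted, in repeated rounds. The chromosome X medians after such removal came from the log2 fold change, treated in the same way.

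The rule for named genes, fixed before the data were examined, took NPTX1 and the tested members of its list, the 12 highest and 12 lowest log2 fold changes among called genes at 2 CPM or more with both hairpins on the same side, the 5 highest and 5 lowest ratios for each hairpin and for their difference, and up to 4 members of each list with the smallest p. Some genes that this rule takes are not reported here. As no test was made for single hairpins, the second part ranked genes by ratio alone. LY75, VEGFA, CXCL8, ALB, COL1A1, COL1A2 and the genes of the protocadherin, mitochondrial ribosome, keratin and GALNT families were named after their values were seen. Alternatives were other scalings, filters, pseudocounts, list statistics and preset correlations, and leaving out chromosome X; apart from the adjustment over all genes with a p, they were chosen after the data were seen. The analysis used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.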

Results

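The data were RNA-seq measurements of liver tumours grown from PANC1 LM3 cells. PANC1 is an established human pancreatic ductal carcinoma cell line, and PANC1 LM3 is a liver-metastatic derivative of it, of generation 3. The cells expressed a control hairpin (shCTRL) or 1 of 2 short hairpin RNAs directed at NPTX1 (shNPTX1_3 and shNPTX1_4). For each tumour group 500000 cells were placed in the spleen on day 1, and RNA was taken from the liver tumours on day 21. There were 4 libraries of shCTRL, 3 of shNPTX1_3 and 4 of shNPTX1_4. They are described as biological replicates, without saying whether each came from its own animal. The DESeq2 p-values therefore measure only the spread between these libraries, which may be partly technical. The p-values of limma's cameraPR, of Fisher's exact test and of the permutations compare genes or gene positions. They do not measure whether a list moved alike in each library, so a single library could shift a whole list. The authors' deposited table gave, for 23434 genes or transcripts, the authors' mean normalized count of each group and 1 comparison, the 7 knockdown libraries over the 4 control libraries. Values of single libraries were not analysed here, so group means stand without an SD, and the error of a change is the standard error in the authors' deposited table. Steps of a single read in the low group means placed the libraries at 13000000 to 41200000 reads on genes in shCTRL, 10800000 to 24000000 in shNPTX1_3 and 16600000 to 26100000 in shNPTX1_4.

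NPTX1, which encodes the secreted neuronal pentraxin 1, was lower in the tumours of both hairpins. In the authors' deposited table, the authors' mean of NPTX1 was 103 normalized counts in shCTRL, 46.5 in shNPTX1_3 and 38.4 in shNPTX1_4. Its log2 fold change, knockdown over control, was -1.26 with a standard error of 0.24 in the authors' deposited table (DESeq2 adjusted p = 3.65e-06), or 0.417-fold. The log2 ratio to control from the authors' deposited table was -1.13 with shNPTX1_3 and -1.40 with shNPTX1_4, and the difference between the hairpins for this gene alone was not tested with single libraries. Among the relatives and partners of NPTX1, the neuronal pentraxin receptor NPTXR also fell, with a log2 fold change of -0.59 in the authors' deposited table (DESeq2 adjusted p = 2.0e-05). The long pentraxin PTX3 rose, with a log2 fold change of 0.86 in the authors' deposited table (standard error 0.30, DESeq2 adjusted p = 0.020). Its authors' means in the authors' deposited table were 66.6 normalized counts in shCTRL, 176 in shNPTX1_3 and 78.9 in shNPTX1_4. AMIGO2, a cell adhesion protein, rose 6.07-fold, from an authors' mean of 138 to 653 and 980.5 normalized counts in the authors' deposited table (DESeq2 adjusted p = 3.23e-46). NPTX2 and the AMPA receptor subunits GRIA1, GRIA2, GRIA3 and GRIA4 did not pass the test in the authors' deposited table, with DESeq2 adjusted p-values of 0.806, 0.494, 0.596, 0.863 and 0.115. Of the 9 tested members of the pentraxin and AMPA receptor list, 2 rose and 2 fell in the authors' deposited table, and the same counts held adjusted over the list alone. The list as a whole was not called (limma's cameraPR on the Wald statistics of the authors' deposited table, adjusted p = 0.764), and its median of -0.21 differed in sign from its mean of 0.09 and from the test. CRP, APCS and PTX4 had no adjusted p in the authors' deposited table.

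The main comparison asked which genes differed between tumours of NPTX1 knockdown cells and control tumours. Among the largest increases, HGF, the ligand of the MET receptor, rose 9.20-fold (log2 fold change 3.20, standard error 0.21) in the authors' deposited table, with authors' means of 71.7 normalized counts in shCTRL, 781 in shNPTX1_3 and 553 in shNPTX1_4. EDIL3, a secreted integrin ligand, rose 8.18-fold in the authors' deposited table (standard error of the log2 fold change 0.19). Among the largest decreases, the proteoglycan versican (VCAN) had authors' means of 491, 89.0 and 103 normalized counts in the authors' deposited table, and the basement membrane protein FREM2 had 730.1, 124 and 136. PRDM1, a transcriptional repressor, and TIMP2, an inhibitor of matrix metalloproteinases, fell by 2.21 and 2.10 on the log2 scale in the authors' deposited table.

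Across the authors' deposited table, 5027 of 18426 named genes with an adjusted p passed 0.05 by DESeq2 (27.3%). Of these, 2913 were higher in the knockdown tumours and 2114 lower, a share of 57.9% higher. With each group scaled to the same total, which lowers every log2 fold change by 0.0661, the split was 2132 higher and 3017 lower, 41.4% higher, so the balance between the directions depended on the scaling. Most changes were small, with a median absolute log2 fold change of 0.47 among the called genes of the authors' deposited table. By the authors' deposited table, 385 called genes were at least 2-fold higher and 308 at least 2-fold lower.

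Among called genes with an authors' mean of at least 2 CPM and both hairpins on the same side of control, the 12 with the largest increases included LY75-CD302, MMP1, SPTSSB, TRPA1, HGF, EDIL3, ABCG2, GALNT5, CAVIN2, MUC5B and RCSD1, with log2 fold changes from 5.56 down to 2.61 in the authors' deposited table. MMP1, an interstitial collagenase, had authors' means of 31.7 normalized counts in shCTRL, 689.5 in shNPTX1_3 and 119 in shNPTX1_4 in the authors' deposited table, and a standard error of 0.74 on a log2 fold change of 3.52. TRPA1, a cation channel, had authors' means of 17.1, 91.4 and 206 normalized counts in the authors' deposited table, and ABCG2, a drug efflux transporter, had 11.3, 108 and 75.9. GALNT5, which starts mucin-type O-glycosylation, rose by 2.86 in the authors' deposited table, and MUC5B, a gel-forming mucin, by 2.69. LY75-CD302 is a readthrough of LY75 and CD302, with authors' means of 2.30, 236 and 23.8 normalized counts in the authors' deposited table, and its reads cannot be told from those of its parts. LY75 alone had authors' means of 253, 649 and 332 normalized counts in the authors' deposited table.

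Within the same limits of level and side, the 12 genes with the largest decreases were CEP295NL, FREM2, SLC4A4, VCAN, ZNF618, PRDM1, SEMA6B, TLR2, TIMP2, MN1, OSBPL6 and TRIM9, with log2 fold changes from -2.47 to -1.94 in the authors' deposited table. VCAN had a log2 fold change of -2.34 with a standard error of 0.11 in the authors' deposited table (DESeq2 adjusted p = 3.6e-98), and FREM2 had -2.46 with 0.13 (7.56e-81). PRDM1 went from an authors' mean of 1276 normalized counts to 272 and 278 in the authors' deposited table, and TIMP2 from 1414 to 416 and 267. SLC4A4, a sodium bicarbonate cotransporter, had authors' means of 106, 29.3 and 13.7 normalized counts in the authors' deposited table. TLR2, an innate immune receptor, had the widest error of these 12, with a log2 fold change of -2.14, a standard error of 0.82 and a DESeq2 adjusted p of 0.0364 in the authors' deposited table. Several of these genes share sequence with a neighbour: CEP295NL lies within TIMP2 on the same strand, AMIGO2 overlaps PCED1B and PRDM1 overlaps ATG5 on the other strand, and VCAN, FREM2, EDIL3, CAVIN2, MUC5B, RCSD1, TRPA1, TIMP2 and TRIM9 have antisense genes. The strand setting of the authors' counting is not given in the sources used here, so reads of the shared stretches are uncertain.

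**Figure D1:**
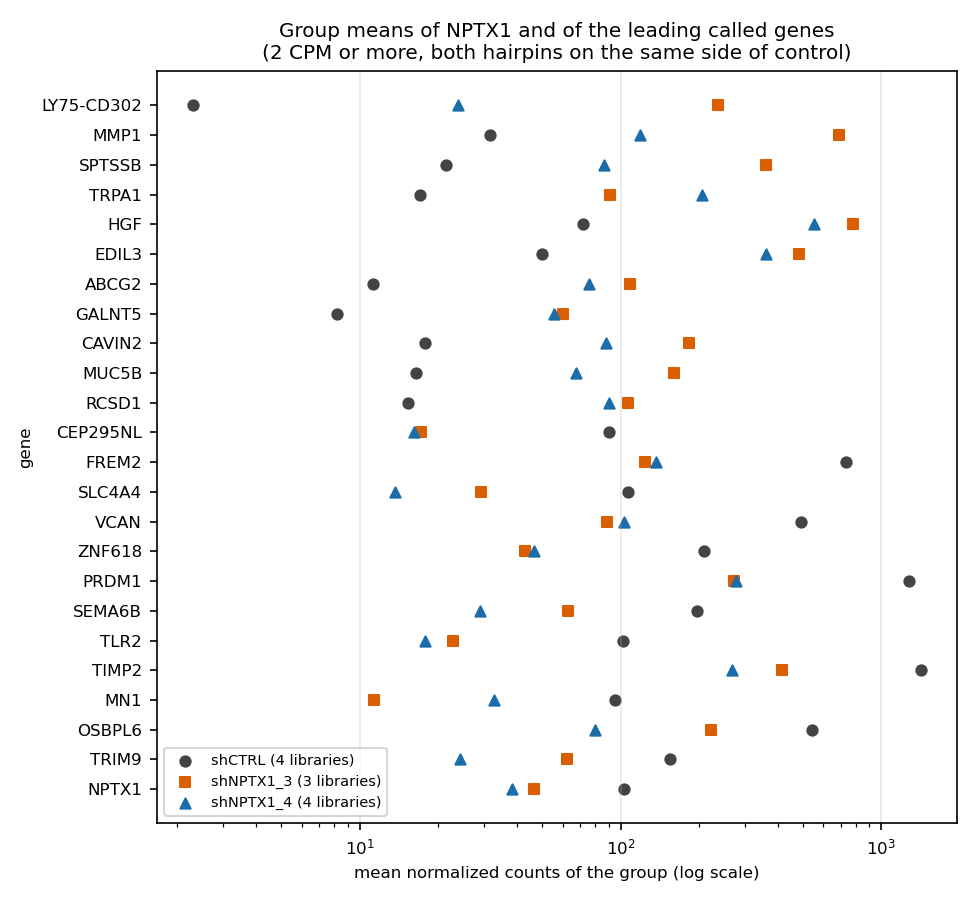
Authors' mean normalized counts (log scale) of NPTX1, of 11 of the 12 genes with the largest increases and of the 12 with the largest decreases among called genes at 2 CPM or more with both hairpins on the same side of control, from the authors' deposited table, with 1 symbol per group (circles shCTRL, squares shNPTX1_3, triangles shNPTX1_4) and no error bars, since the table holds group means. By this choice of genes, both knockdown groups lie above control for the upper 11 genes and below it for the lower 12. Nearly all called genes at this level met the limit of side, 4583 of 4585. In libraries simulated with no change, 99.9% of genes at an unadjusted p under 0.05 met it too. Both knockdown groups also lie below control for NPTX1, where 103 normalized counts in shCTRL stand against 46.5 and 38.4.

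Genes of lipid and energy metabolism rose as groups. Of 24 cholesterol synthesis genes, 14 rose and 0 fell in the authors' deposited table, or 16 and 0 adjusted over the list alone, with a median log2 fold change of 0.37 (limma's cameraPR, adjusted p = 1.74e-05). The sterol dehydrogenase NSDHL rose by 0.91 on the log2 scale in the authors' deposited table, MSMO1 by 0.68 and the sterol isomerase EBP by 0.65. Of 30 nuclear-encoded genes of oxidative phosphorylation, 10 rose and 0 fell in the authors' deposited table, or 12 and 0 adjusted over the list alone (cameraPR adjusted p = 2.56e-04, median 0.19). COX7C, a subunit of cytochrome c oxidase, rose most among its named members, from an authors' mean of 736 to 1892 and 2002 normalized counts in the authors' deposited table, and the complex I subunits NDUFA1, NDUFB3 and NDUFB8 rose by 0.75, 0.62 and 0.40. Of 17 glycolysis genes, 6 rose and 1 fell in the authors' deposited table, or 7 and 1 adjusted over the list alone (cameraPR adjusted p = 0.0173, and 0.0714 with the preset correlation raised to 0.05). PGK1 rose by 0.76, the pyruvate kinase gene PKM by 0.47, ALDOC by 0.53 and the lactate exporter SLC16A3 by 0.30 in the authors' deposited table, where ALDOC and SLC16A3 lost their calls under total-count scaling. Of 32 cytosolic ribosomal protein genes, 12 rose and 0 fell in the authors' deposited table, or 13 and 0 adjusted over the list alone (cameraPR adjusted p = 7.40e-04). Examples were RPS16, RPS3, RPL23 and RPL8, with log2 fold changes of 0.75, 0.53, 0.41 and 0.40 in the authors' deposited table, and ribosomal genes and COX7C have processed pseudogenes that can share reads. NSDHL, EBP, NDUFA1 and PGK1 lie on chromosome X, where 210 of 423 genes at 2 CPM or more rose in the authors' deposited table. Across 12735 genes, which are not independent replicates, the log2 fold change of the authors' deposited table fell with transcript length (Spearman's rho -0.199). With level, length and GC content removed the cameraPR adjusted p was 8.1e-04 for cholesterol synthesis, 0.0758 for oxidative phosphorylation, 0.259 for glycolysis and 0.321 for the ribosomal proteins.

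Of 20 angiogenic factors, 9 rose and 1 fell in the authors' deposited table, the same counts as adjusted over the list alone, and the median log2 fold change was 0.60 (limma's cameraPR, adjusted p = 5.97e-05). Besides HGF, the lymphangiogenic factor VEGFC rose by 1.04 in the authors' deposited table, the vasoactive peptide gene ADM by 0.91 and the semaphorin SEMA3C by 0.60. VEGFA also rose, with authors' means of 1574, 5126 and 2412 normalized counts in the authors' deposited table. Of 30 collagens and matrix proteases, 12 rose and 3 fell in the authors' deposited table, or 12 and 4 adjusted over the list alone (cameraPR adjusted p = 7.40e-04). Fibronectin (FN1) rose by 1.88 and the fibrillar collagen gene COL5A2 by 1.79 in the authors' deposited table, while TIMP2 fell by 2.10. Of 23 mesenchymal genes, 7 rose and 4 fell in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.0419, 0.148 with the preset correlation at 0.05 and 0.0758 with level, length and GC content removed). The median log2 ratio of the mesenchymal list in the authors' deposited table was 0.95 with shNPTX1_3 and -0.18 with shNPTX1_4. FN1 and S100A4 rose, S100A4 by 1.84 in the authors' deposited table, while N-cadherin (CDH2) fell by 0.84 and the collagen crosslinking enzyme gene LOX by 0.82. Of 24 epithelial genes, 7 rose and 4 fell in the authors' deposited table, with the same counts adjusted over the list alone, and the list was not called (cameraPR adjusted p = 0.379; median -0.00, mean 0.36). Its members moved apart in the authors' deposited table: keratin 19 (KRT19) rose by 2.30, MAL2 by 4.25, and the transcription factor ELF3 3.90-fold, while desmoplakin (DSP) fell by 1.40, from an authors' mean of 7459 to 3198 and 2561 normalized counts. MAL2 did not meet the limits of level and side set for the largest increases above.

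Of 28 hypoxia response genes, 14 rose and 2 fell in the authors' deposited table, with the same counts adjusted over the list alone (limma's cameraPR, adjusted p = 0.0078, and 0.0674 with the preset correlation at 0.05). BNIP3, a mitophagy receptor, rose by 0.92 and the collagen prolyl hydroxylase subunit P4HA1 by 0.43 in the authors' deposited table. Of 22 NF-kB and inflammatory genes, 9 rose and 0 fell in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.0082, and 0.0667 with the preset correlation at 0.05). CSF1, a macrophage growth factor, rose by 1.79 in the authors' deposited table, the chemokine gene CCL20 by 1.71, CSF2 by 1.08 and BIRC3 by 0.80. The median log2 ratio of the NF-kB list in the authors' deposited table was 1.01 with shNPTX1_3 and -0.05 with shNPTX1_4. Of 26 endoplasmic reticulum and amino acid stress genes, 11 rose and 2 fell in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.0053, and 0.0606 with the preset correlation at 0.05). The members moved in different directions in the authors' deposited table: the chaperone genes HSPA5, PDIA4 and CRELD2 rose by 0.64, 0.64 and 0.78, and PHGDH, the entry enzyme of serine synthesis, fell by 1.38. With level, length and GC content removed, the cameraPR adjusted p was 0.0758 for each of the hypoxia, NF-kB and endoplasmic reticulum lists. Of 21 neuronal and synaptic genes, 2 rose and 6 fell in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.0235, 0.10 with the preset correlation at 0.05 and 0.0509 with level, length and GC content removed). NCAM1 fell by 0.84, NLGN2 by 0.73, MAP2 by 0.68 and DLG4 by 0.62 in the authors' deposited table.

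The 6 other tumour lists besides the pentraxin and epithelial lists were not called by limma's cameraPR, with adjusted p-values of 0.115 for YAP-TEAD targets, 0.420 for TGF-beta targets, 0.764 for RAS-ERK output, 0.764 for the interferon response and 0.874 for p53 targets and for the cell cycle. Of 32 cell cycle genes, 6 rose and 3 fell in the authors' deposited table, with the same counts adjusted over the list alone. MKI67 fell by 0.69 and the thymidylate synthase gene TYMS by 0.48 in the authors' deposited table, while CCNB1 and E2F1 rose by 0.37 and 0.27, calls that both lost under total-count scaling. Of 22 p53 targets, 4 rose and 2 fell in the authors' deposited table, with the same counts adjusted over the list alone; GADD45A rose by 1.30, TP53I3 rose by 0.35, BTG2 fell by 0.98 and BCL2L11 fell by 0.53, and the list's median of -0.02 had the other sign than its mean of 0.0036. Of 25 YAP-TEAD targets, 6 rose and 4 fell in the authors' deposited table, or 7 and 4 adjusted over the list alone, among them AMOTL1, which rose by 1.64, and ASAP1, which fell by 0.69. Of 22 TGF-beta targets, 3 rose and 3 fell in the authors' deposited table, with the same counts adjusted over the list alone; TGFB2 rose by 0.92 and LTBP3 by 0.65, and TGFB1 fell by 0.65 and ID2 by 0.74. Of 27 RAS-ERK genes, 5 rose and 4 fell in the authors' deposited table, with the same counts adjusted over the list alone; the EGFR ligand gene AREG rose by 2.03 and DUSP4 by 1.70, and CCND1 fell by 0.55 and SPRY4 by 0.58. Of 32 interferon response genes, 3 rose and 1 fell in the authors' deposited table, or 2 and 1 adjusted over the list alone; USP18 rose by 0.76 and PSMB8 by 0.67, and OAS3 fell by 0.30. PSMB8 lost its call under both other scalings and with the adjustment over all genes with a p. The medians of the cell cycle, interferon and RAS-ERK lists, 0.01, 0.04 and 0.04 in the authors' deposited table, fall below 0 under total-count scaling.

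**Figure D2:**
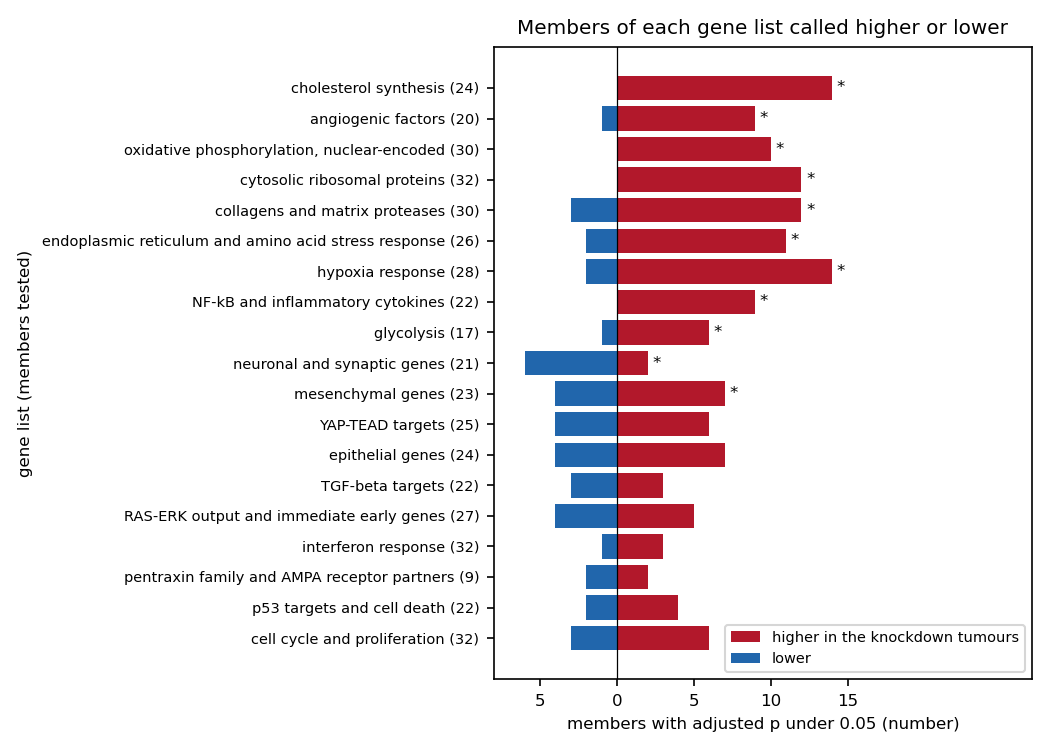
Number of members of each gene list that were higher (right) or lower (left) in the knockdown tumours at an adjusted p under 0.05 in the authors' deposited table, with the number of tested members in parentheses and a star for lists called by limma's cameraPR. Cholesterol synthesis had 14 members higher and 0 lower, and the neuronal list had 2 higher and 6 lower.

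Hepatocyte transcripts were scarce among these values for human genes. Albumin (ALB), the most abundant hepatocyte transcript, had authors' means of 0.784, 0.616 and 0.284 normalized counts in the authors' deposited table. Hepatocyte markers summed to 36.2, 42.2 and 29.9 CPM in shCTRL, shNPTX1_3 and shNPTX1_4 of the authors' deposited table, macrophage markers to 52.6, 53.2 and 43.9, and endothelial markers to 56.7, 49.1 and 46.5. Fibroblast markers summed to 175, 398 and 211 CPM in the authors' deposited table, lymphocyte markers to 13.7, 10.3 and 10.8, neutrophil markers to 13.3, 11.3 and 11.1 and erythroid markers to 218, 194 and 282. The 7 marker lists were not called by limma's cameraPR, with adjusted p-values from 0.572 to 0.832. Single markers passed the test in the authors' deposited table: among 16 hepatocyte markers TDO2, APOA1 and TF rose, among 13 fibroblast markers COL3A1, PDGFRA and LUM rose and THY1 fell, and LAPTM5 of 10 macrophage, ENG of 15 endothelial and CD4 of 9 lymphocyte markers fell. Adjusted over the list alone the fibroblast counts became 4 and 2, and the others stayed at 3 and 0 for hepatocytes and 0 and 1 for macrophages, endothelium and lymphocytes. None of the 6 neutrophil and 5 erythroid markers passed in either way. COL3A1 rose by 2.32 in the authors' deposited table, with authors' means of 731, 5517 and 2247 normalized counts, and it belongs to the collagen list as well. COL3A1 alone made the fibroblast sums higher in the knockdown groups. Without COL3A1, the summed CPM of the other tested fibroblast markers was not above control in either knockdown group. The mitochondrially encoded transcripts had 0 members among the rows used here.

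Each hairpin alone was compared with control by size, since the authors' deposited table holds no test for single hairpins. Among 14127 genes at 2 CPM or more with no group at 0, 417 were at least 2-fold higher and 214 at least 2-fold lower with shNPTX1_3, by log2 ratios of group means in the authors' deposited table with a pseudocount of 1. With shNPTX1_4, 208 were at least 2-fold higher and 174 lower in the authors' deposited table. Libraries simulated with no change in any group gave 32.6 such genes with shNPTX1_3 and 25.2 with shNPTX1_4. Among these 14127 genes, the highest log2 ratios with shNPTX1_3 in the authors' deposited table included those of AMY2A (6.89), LY75-CD302 (6.17), MMP1 (4.40) and SPTSSB (4.02). The lowest in the authors' deposited table were those of the readthrough ATP5J2-PTCD1 (-5.72), the receptor tyrosine kinase gene ERBB4 (-3.11), the SRC family kinase gene FYN (-3.01), MN1 (-2.95) and the Notch effector HEY1 (-2.81). With shNPTX1_4 the highest log2 ratios in the authors' deposited table were those of TRPA1 (3.52), TPD52L1 (2.93), HGF (2.93), LY75-CD302 (2.91) and the netrin NTN4 (2.82). The lowest in the authors' deposited table were those of SLC4A4 (-2.87), OSBPL6 (-2.75), SEMA6B (-2.72), TRIM9 (-2.62) and TLR2 (-2.46). AMY2A, a pancreatic amylase gene with close copies that can share reads, had authors' means of 1.12 normalized counts in shCTRL, 251 in shNPTX1_3 and 0.668 in shNPTX1_4 in the authors' deposited table, so its increase stood in 1 hairpin group.

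Many genes lay on the same side of control with both hairpins. Of the 14127 genes, 134 were at least 2-fold higher and 69 at least 2-fold lower with each hairpin in the authors' deposited table, 203 in all, against 7.8 in simulated libraries with no change and 6.14 and 2.64 for independent lists. HGF, AMIGO2 and EDIL3 were among the first kind in the authors' deposited table, with log2 ratios of 3.43 and 2.93, 2.24 and 2.82, and 3.24 and 2.82 with shNPTX1_3 and shNPTX1_4. FREM2, VCAN, PRDM1 and NPTX1 were among the second, NPTX1 with -1.13 and -1.40. Across genes, which are not independent replicates, the log2 ratios of the hairpins in the authors' deposited table had a Pearson r of 0.657, against 0.454 in simulated libraries that share the same controls with no change. Their covariance was 0.132, against 0.0175 simulated, a difference of 0.114. The shared sign of 76.2% of genes stood against 64.9% simulated. The simulated values already contain the sharing of controls. A difference that sits in the control libraries, for a reason other than NPTX1, is absent from the simulations. It would move both ratios alike, so part of these excesses may come from it. The controls were not split because the table holds their mean.

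The group means of the 2 hairpins also lay apart for some genes. Values of single libraries were not analysed, so a single library could make such a gap. HEY1 had authors' means of 186 normalized counts in shCTRL, 25.7 in shNPTX1_3 and 219 in shNPTX1_4 in the authors' deposited table, and ERBB4 had 216, 24.1 and 135. Periostin (POSTN), a matrix protein, had authors' means of 38.7, 239 and 21.5 normalized counts in the authors' deposited table, and NNMT had 23, 111 and 8.03. By the authors' deposited table, 122 genes were at least 2-fold higher and 257 at least 2-fold lower with shNPTX1_4 than with shNPTX1_3, against 36.0 genes in libraries simulated with the hairpins alike. Among genes at 2 CPM or more with no group at 0, the highest log2 ratios of shNPTX1_4 over shNPTX1_3 in the authors' deposited table were those of ATP5J2-PTCD1 (4.42), LINC00473 (3.66), HEY1 (3.04), PLAGL1 (2.63) and ERBB4 (2.44). The lowest in the authors' deposited table were those of AMY2A (-7.24), NNMT (-3.63), POSTN (-3.42), LY75-CD302 (-3.26) and the guanine nucleotide exchange factor gene VAV3 (-2.93). A z per gene, rebuilt from the standard errors of the authors' deposited table, gave 0 genes after Benjamini-Hochberg adjustment and 3384 at an unadjusted p under 0.05. Those standard errors already contain the difference between the hairpins, so they are too wide for this purpose. Of the 19 gene lists, 11 differed between the hairpins by limma's cameraPR on that z, and 8 with the preset correlation at 0.05. By limma's cameraPR, NF-kB and inflammatory genes were lower with shNPTX1_4 in 16 of 16 members (adjusted p = 4.42e-10), interferon response genes in 28 of 29 (adjusted p = 4.15e-10), and cell cycle genes were higher in 29 of 32 (adjusted p = 4.66e-07). CXCL8 had authors' means of 266, 1197 and 386 normalized counts and MKI67 had 14460.1, 6978 and 10479.7 in the authors' deposited table.

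**Figure D3:**
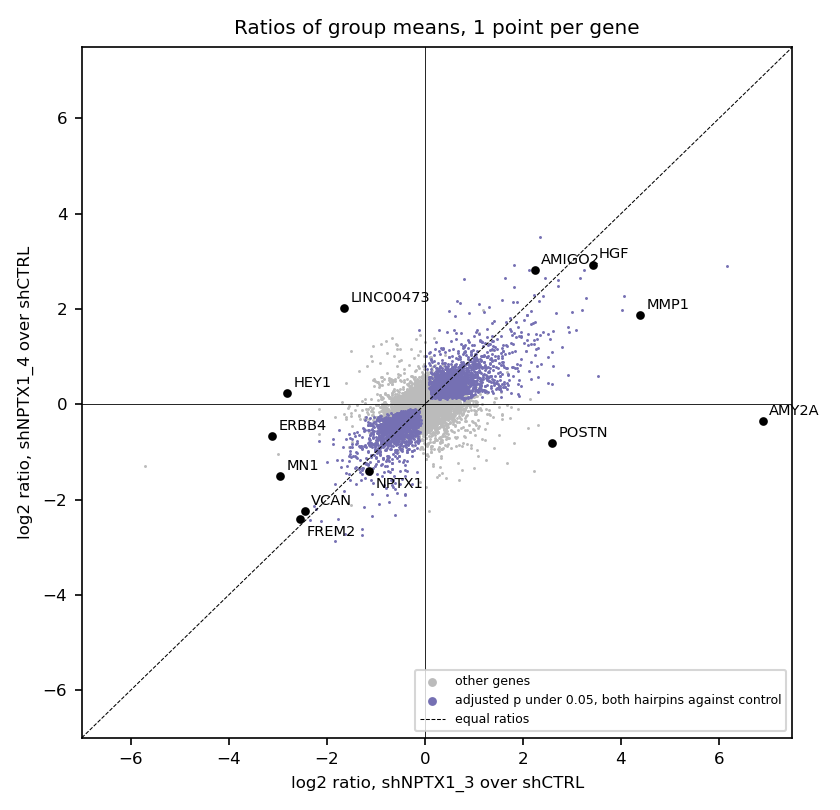
Log2 ratio of group means to shCTRL, with a pseudocount of 1, for shNPTX1_3 (horizontal) and shNPTX1_4 (vertical), with 1 point per gene for 14127 genes at 2 CPM or more and the line of equal ratios dashed; coloured points passed an adjusted p of 0.05 in the authors' deposited table, and black points are named. HGF at 3.43 and 2.93 and VCAN near -2.45 and -2.24 lie close to the line, while AMY2A at 6.89 and -0.35 and HEY1 at -2.81 and 0.23 lie far from it.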

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

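The comparison of the lists between the hairpins was planned, while its form, a test on a rebuilt z, and both tests of its explanations were chosen after the values had been seen. The lists below were singled out because the same contrast, knockdown against control, differed between the hairpins by limma's cameraPR on that z.

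Inflammatory and interferon genes were lower in shNPTX1_4 than in shNPTX1_3 tumours. NF-kB and inflammatory genes had a median log2 ratio of -0.86, shNPTX1_4 over shNPTX1_3 (limma's cameraPR, adjusted p = 4.42e-10), and interferon response genes -0.64 (adjusted p = 4.15e-10). CXCL8 had authors' means of 266, 1197 and 386 normalized counts in shCTRL, shNPTX1_3 and shNPTX1_4 in the authors' deposited table. Matrix and mesenchymal genes moved the same way: collagens and matrix proteases were lower in 21 of 24 members (limma's cameraPR, adjusted p = 2.82e-06), and mesenchymal genes in 17 of 21 (adjusted p = 1.87e-05). Cell cycle genes went the other way, higher in shNPTX1_4 in 29 of 32 members, with a median log2 ratio of 0.28 (limma's cameraPR, adjusted p = 4.66e-07).

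Of the other lists, TGF-beta targets were lower with shNPTX1_4 in 15 of 20 members (limma's cameraPR, adjusted p = 3.4e-04), epithelial genes in 12 of 15 and p53 targets in 16 of 22 (adjusted p = 0.00278 for each). Glycolysis genes (limma's cameraPR, adjusted p = 0.0156) and hypoxia response genes (adjusted p = 0.0230) were lower, and neuronal and synaptic genes were higher (adjusted p = 0.0409). Fibroblast and stellate cell markers were lower in 6 of 8 members, with a median of -1.13 (limma's cameraPR, adjusted p = 0.0281). With the preset correlation at 0.05, the adjusted p was 0.106 for hypoxia and neuronal genes, 0.0666 for glycolysis and 0.0709 for the fibroblast markers, and the other 8 lists kept their calls. On ranks the neuronal list (0.0717) and the fibroblast markers (0.122) did not pass. Angiogenic factors did not pass (adjusted p = 0.0507).

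As a pattern, the rebuilt z of the hairpin difference spread wider than in libraries simulated with the hairpins alike. Its SD was 1.57, against at most 1.01 in those libraries. Each gene was simulated on its own, so spread that genes of a library share is absent there. The comparison cannot tell such spread from a difference between the hairpins. Whether the shNPTX1_3 tumours held more RNA of host fibroblasts stays open. COL1A1, the main fibroblast collagen, had a log2 ratio of 0.54 (0.538, standard error 0.227), shNPTX1_4 over shNPTX1_3, with a lower bound of 0.0949. This single gene went the other way but cannot decide the question. The fibroblast markers as a set were lower with shNPTX1_4, in 6 of 8 members with a median of -1.13. COL1A2 had authors' means of 17.8 and 17.5 normalized counts with shNPTX1_3 and shNPTX1_4 in the authors' deposited table, while COL3A1 had 5517 and 2247. It also stays open whether the difference comes from the hairpins, from the cell population of each, or from the handling of each tumour group. Spread that genes of a library share is a further possibility. These cannot be told apart without a second population per hairpin and values of single libraries.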

How the results depend on the processing

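The adjustment over all genes with a p was planned, and all other alternatives were chosen after the data were seen. Under 5 alternatives the main comparison called 4764 (adjustment over all genes with a p) to 5149 genes (total-count scaling), against 5027. The share higher was 41.4% under total-count scaling, 52.0% with the median log2 fold change set to 0, and 56.4% without chromosome X. NPTX1 kept its direction and call throughout, from -1.26 to -1.33. For 138 named genes, 532 of 540 values kept direction and call, 7 lost the call, 1 gained it and 0 reversed. With neither the minimum nor the limit to genes with no group at 0, which were dropped together, the counts of genes at least 2-fold apart rose to 1797 for shNPTX1_3, 1047 for shNPTX1_4, 1296 between the hairpins and 493 in the same direction with each, and the cause was not tested. At 1 CPM they were 791, 474, 479 and 249, and with pseudocounts of 0.5 and 4 they stayed between 599 and 640 for shNPTX1_3, 361 and 386 for shNPTX1_4, 360 and 379 between hairpins and 193 and 206 in the same direction.

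Of 11 gene lists called by limma's cameraPR, 10 were called on ranks and 11 without chromosome X. At a preset correlation of 0.05, 5 were called, with adjusted p-values of 0.148 for mesenchymal, 0.0674 for hypoxia, 0.0714 for glycolysis, 0.0667 for NF-kB, 0.0606 for endoplasmic reticulum stress and 0.10 for neuronal genes. On log2 fold changes 7 were called, epithelial genes among them (0.0096), with 0.153 for glycolysis and neuronal genes, 0.0618 for oxidative phosphorylation and 0.0731 for endoplasmic reticulum stress and ribosomal proteins. With level, length and GC content removed 3 were called, with 0.0758 for mesenchymal, hypoxia, oxidative phosphorylation, NF-kB and endoplasmic reticulum stress genes, 0.259 for glycolysis, 0.0509 for neuronal genes and 0.321 for ribosomal proteins. On ranks the mesenchymal list had 0.0864. The larger preset correlation widens the error by construction; for the others the cause was not tested. The 7 cell type lists were called under none of these.

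No paired analysis was possible because the table holds group means, and the replicate numbers are carried by no column. For the same reason the planned edgeR, voom, other normalizations, fits of the compared groups only, hepatocyte covariate, fits without single libraries, estimated correlation, fry and split of the controls were not run, and other splits of the libraries could not be counted. Depth limits low genes most. TLR2, AMY2A and LY75-CD302 carried standard errors of 0.82, 2.49 and 1.54 in the authors' deposited table. Those errors also contain any difference between the hairpins, and the part of depth in them was not tested.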

Other observations

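The tests of gene families, of chromosome X and of transcript length reported here were chosen after the data were seen, and 4 of the explanations below were set down before their test: gene positions, expression level, a difference in the controls, and RNA integrity.

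Gene families were formed by a shared symbol stem, except that the PCDHA, PCDHB and PCDHG genes, of several stems, were joined by hand. Among 129 such families, 16 were called by limma's cameraPR, and the joined family alone at a preset correlation of 0.05. That family was the clustered protocadherins, cell surface adhesion proteins of the PCDHA, PCDHB and PCDHG genes: of 54 tested members, 38 fell and 0 rose in the authors' deposited table, with a median log2 fold change of -0.87 (limma's cameraPR, adjusted p = 8.13e-19, and 1.51e-07 at 0.05). With shNPTX1_3 the median log2 ratio was -0.71 and with shNPTX1_4 -0.94. The PCDHA and PCDHG genes share constant exons, so their single values are uncertain, while PCDHB genes do not share them. Shared reads can also make their calls alike, which the test does not allow for. By cluster, 21 of 22 PCDHG, 11 of 17 PCDHB and 5 of 13 numbered PCDHA genes fell in the authors' deposited table. Of the genes of the mitochondrial ribosome, 22 of 52 MRPL genes and 17 of 30 MRPS genes rose and 0 fell in the authors' deposited table, with medians of 0.27 for each (limma's cameraPR, adjusted p = 2.56e-04 and 0.00248, and 0.151 for each at 0.05). With level, length and GC content removed, the adjusted p was 0.0400 for MRPL and 0.0912 for MRPS genes.

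Of 24 keratins, 8 rose, 1 fell and 15 were not called in the authors' deposited table, with a median log2 fold change of 0.77 (limma's cameraPR, adjusted p = 0.0129, and 0.179 at 0.05). Their median log2 ratio was 1.13 with shNPTX1_3 and 0.14 with shNPTX1_4. KRT8 had authors' means of 8293, 30512 and 14002 normalized counts in shCTRL, shNPTX1_3 and shNPTX1_4 in the authors' deposited table, its partner KRT18 had 5877, 16989 and 9450.4, and KRT17 fell by 0.79 on the log2 scale. KRT8 and KRT18 have many processed pseudogenes that can share reads. Of 16 GALNT genes, which start mucin-type O-glycosylation, 7 rose and 1 fell in the authors' deposited table (limma's cameraPR, adjusted p = 0.0129, and 0.155 at 0.05). GALNT5 and GALNT18 rose by 2.86 and 1.98 in the authors' deposited table, and GALNT14 fell by 2.02.

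Genes of chromosome X were higher as a group in the knockdown tumours. Of 423 X genes at 2 CPM or more, 210 rose and 17 fell in the authors' deposited table, 49.6% rising against 18.8% of 13350 autosomal genes (Fisher's exact test, p = 1.34e-44, over genes, which are not independent). Their median log2 fold change was 0.35 in the authors' deposited table, against 0.02 on autosomes. The shift was uneven, from 0.00 to 0.71 over 14 windows of neighbouring genes, and highest in the last window, from NAA10 to TMLHE, where 29 of 33 genes rose in the authors' deposited table. Of 449 windows on all chromosomes, 12 lay beyond the permuted range, 9 of them on X. The others were lower: HARS2 to PCDHGA10 on chromosome 5, which holds protocadherins (median -0.81), and PPP1R14A to SAMD4B (-0.27) and LILRB3 to ISOC2 (-0.26) on chromosome 19, where 63 of 985 genes rose and 182 fell in the authors' deposited table (median -0.10).

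For this X pattern, neighbouring genes drawn by chance are argued against by 0 of 10000 permutations of gene positions with as high a median (p = 0.0001, the smallest they can give). Level, length and GC content are argued against by a median of 0.34 (0.343) after their removal. An effect of 1 hairpin alone is argued against for the last 5 windows, where the lower of the hairpin medians was 0.538. These windows had the highest medians and were set apart after the values were seen, which weakens the argument. An effect of 1 hairpin alone stays open for the first 9 windows, where shNPTX1_3 had 0.0615 and shNPTX1_4 0.244. Both hairpin medians were at least 0.2 in 3 of those 9. It stays open as well for all X genes, where the lower median of 0.265 fell to 0.187 at 1 CPM. The highest and lowest windows differed by 0.711. A segment that differs in copies or silencing between the knockdown lines and the control line could give this. The values do not tell which side changed, since both hairpins were compared with the same control. Expression alone cannot tell this hypothesis from regulation of the genes there.

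Longer transcripts were lower in the knockdown tumours. Across 12735 genes, Spearman's rho of transcript length and log2 fold change was -0.199, and the median log2 fold change went from 0.13 in the shortest transcripts (177 to 911 nucleotides) to -0.06 in the longest (3597 to 27174 nucleotides). Expression level is argued against by a median rho of -0.223 within 10 bins of like level. A difference that sits in the control libraries is consistent with rho of -0.188 and -0.182 for shNPTX1_3 and shNPTX1_4 against control and 0.0609 between the hairpins, which a common effect of knockdown would give as well. A difference in RNA integrity or fragment length between the libraries stays open, since the trend of -0.199 in group means cannot be told apart from regulation.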
